A study of Sus scrofa with 6 samples.

How the data were processed

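The study profiled RNA from cells of the Small Xiang Pig (Sus scrofa) by sequencing. Per the labels, 6 libraries fell into 3 groups of 2 libraries: PEF, the progenitor fibroblasts, at passage 5; porcine induced pluripotent stem cells (piPSCs) at passage 5 described as Rex1 positive; and piPSCs at passage 10 described as Rex1 negative. RNA was purified on RNeasy Mini columns and libraries were made with the NEBNext Ultra RNA kit, per the labels' protocols. Reads were handled with Bowtie2 2.0.6 and TopHat2 2.0.9 on the susScr3 genome build, per the submitters' processing notes.

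The values used here are FPKM (fragments scaled to gene length and to the mapped fragments of the library) made by the authors, per the file headers, with 1 deposited column per group. The program that made the FPKM, the annotation release and the way in which the 2 libraries of a group were combined are not given in the sources used here. Each value is therefore the authors' group value, with no SD and no n, and no spread between libraries could be computed. All 3 columns were matched to groups by their names.

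The table held 25322 gene IDs. Gene symbols came from a reference table of gene IDs and symbols, which matched 11804 IDs, or 46.6%. IDs without a match kept their ID and entered the counts of genes. IDs of ZFP42 (the gene of Rex1), POU5F1, SOX2 and NANOG were not matched, so these genes are not analysed here and the Rex1 state in the labels was not checked against expression. Coordinates are those of the table, on susScr3, and whether the starts count from 0 or 1 is not given in the sources used here. A position is that of a locus, and 4269 IDs shared a locus with another ID. Of genes at a shared locus, the division of reads between neighbours is uncertain.

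Before the data were examined, limma was planned for values per library. For a table with 1 value per group the plan replaced the test by a description, and that description is reported. Values were taken as log2(FPKM + 1), so a fold derived from a difference understates the difference of low genes. The 13998 IDs with an FPKM of at least 1 in at least 1 group were compared, 8944 of them with a symbol. A gene was counted as higher or lower where 2 groups differed by at least 1 on this scale, a 2-fold difference. No p-value was computed, since genes are not replicates.

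A total of 29 gene lists with 620 genes was fixed before the data were examined, and 435 of these genes had a row. They covered pluripotency (core, naive-associated and primed-associated), epithelial genes, mesenchymal transcription factors, fibroblast and extracellular matrix genes, contractile and smooth muscle genes, and neural, mesoderm, endoderm, trophectoderm and germ cell genes. Others covered DNA methylation, Polycomb, histone deacetylases, histone methyltransferases and demethylases, the cell cycle, p53 targets and senescence, glycolysis, oxidative phosphorylation, LIF and STAT3, FGF and ERK, TGF-beta, activin and BMP, and WNT. Imprinted, interferon, endothelial, immune and stress genes completed the set. For each list with at least 5 compared members, the median difference was placed among the medians of 10000 random lists of the same size, drawn from genes with a symbol and matched in 20 bins of mean expression. A list stood outside the random range where its median lay below percentile 2.5 or above percentile 97.5. With 27 lists per comparison, 5% would lie outside by this construction alone if the members of a list varied independently, as in the random lists. Members that vary together can put more lists outside, so a place outside the range is a description. Lists that share genes are not independent.

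The genes named in the text followed a rule. Rule genes were KLF4 and MYC, found among 6 pluripotency factors set in advance. The 8 highest and 8 lowest differences per comparison among genes with a symbol and an FPKM of at least 5 in the higher group were added. Up to 4 counted members per list with the largest differences, and members of lists going both ways, completed the rule. Names outside it are said to have been chosen after their values were seen. Some genes that met the rule are not reported here.

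The depth of the columns is unknown. Among genes with FPKM under 0.15, the commonest ratio between columns gave a hint of relative depth, with the P5 column at 0.731 times and the P10 column at 1.42 times the depth of PEF. The P10 to P5 ratio was 1.96. These rest on 23 of 589, 23 of 678 and 38 of 774 genes under that FPKM in both columns. The 23, 23 and 38 genes shared a ratio within 0.02 on the log2 scale, and no interval was drawn from them.

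Alternatives were pseudocounts of 0.1 and 5, no filter, a mean FPKM of at least 5, median scaling, quantile normalization, trimmed-mean scaling and a log2 difference of at least 2. After the data were seen, 3 more were added: without IDs listed at 0, with symbols but without small RNA names, and without IDs sharing a locus. The placement of lists with a pseudocount of 5, a mean FPKM of at least 5, trimmed-mean scaling and symbols only was also unplanned and added then. So were the mitochondrial share without ATP8, the tests of PEF RNA over all genes abundant in PEF and the leaving out of single list members. The threshold of 2 does not enter the placement of lists. The procedure was tested on simulated data with 4-fold differences planted in 100 genes per direction among 8944 genes and a noise SD of 0.25 (log2). For P5 minus PEF and P10 minus PEF it found 100% of the planted genes, and for P10 minus P5 it found 99% of the higher and 100% of the lower ones. Of unaltered genes, 0.126%, 0.24% and 0.194% were counted in P5 minus PEF, P10 minus PEF and P10 minus P5. Of 100 unaltered lists, 7%, 5% and 5% lay outside the random range in the same order. The noise SD was assumed and not drawn from the data, and the planted genes had at least 5 FPKM in PEF. Noise was independent between genes, so members of the simulated lists did not vary together. The simulation therefore checks the procedure and gives no error rates for these data. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.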

Results

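Gene expression was measured by RNA sequencing in the progenitor fibroblasts (PEF, passage 5) and in 2 states of the piPSCs derived from them, Rex1 positive at passage 5 (P5) and Rex1 negative at passage 10 (P10). Induced pluripotent stem cells are somatic cells returned to an embryo-like state by reprogramming factors, and Rex1, the product of ZFP42, is a zinc finger protein used as a marker of undifferentiated cells. There was 1 deposited FPKM value per gene and group, so none of the differences has a replicate check. The FPKM summed to 821130 in PEF, 628992 in P5 and 826083 in P10, and 11772, 12586 and 12592 IDs reached an FPKM of 1. Genes of the mitochondrial genome took 15.7% of the sum in PEF, 19.1% in P5 and 31.1% in P10. In P10 the highest value was that of ATP8, 173751, at a locus shared by 3 IDs, against 54233 in PEF and 55142 in P5. With ATP8 left out of the sum as well, a choice made after seeing the data, the other mitochondrial genes took 9.77%, 11.4% and 12.8% in PEF, P5 and P10. Across the 13998 genes compared, Pearson's r of log2(FPKM + 1) was 0.89 between P5 and P10, 0.72 between PEF and P5 and 0.71 between PEF and P10. These are correlations across genes, which are not independent replicates.

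The first comparison, P5 against PEF, asked how early Rex1 positive piPSCs differed from the fibroblasts they came from. Most of the pluripotency, epithelial and cell division genes compared were higher in P5, and most matrix and contractile genes were lower. LIN28A, an RNA-binding protein of early development that is used in reprogramming (ENSSSCG00000003557, chromosome 6, 77358778 to 77371149), had an FPKM of 0.325 in PEF and 299 in P5, a log2 difference of 7.82. KRT8 and KRT18, keratin partners of simple epithelia, were at 5.46 and 3.82 in PEF and at 630 and 749 in P5, KRT18 at a locus shared by 2 IDs. ACTA2, smooth muscle actin (chromosome 14, 109852734 to 109871621), was at 4863 in PEF and 18.4 in P5, and FMOD, a collagen-binding proteoglycan, was at 1699 and 2.58.

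Of 24 pluripotency core genes listed, 7 were compared, without POU5F1, SOX2 and NANOG. All 7 were higher in P5, with a median log2 difference of 5.12 at percentile 100 of the random lists. Of these, 1 was listed at 0 in PEF. DNMT3B, a de novo DNA methyltransferase of early embryonic cells, was at 1.57 in PEF and 159 in P5. CDH1, the epithelial cadherin, was at 0.103 and 48.7, and EPCAM, an adhesion molecule, at 0.227 and 41.6. CDH1 and EPCAM also belonged to the epithelial list, of which 20 of 21 members were higher, with a median of 3.23. Of the higher epithelial members, 2 were listed at 0 in PEF. Both lists stayed outside the random range without IDs listed at 0. Among the cell cycle genes 21 of 21 were higher, with a median of 2.34. The replication licensing gene MCM2 differed by 3.79 and the DNA topoisomerase TOP2A by 2.89.

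The primed-associated list had 8 of 10 members higher and 1 lower, with a median of 2.37. OTX2, a transcription factor of the epiblast and anterior brain, was at 0.312 in PEF and 49.7 in P5, while the WNT antagonist SFRP2 was at 332 and 57.1. Of the naive-associated list 6 of 8 were higher and 1 was lower, with a median of 1.25. Among the higher members, ESRRB, PRDM14 and TCL1A, named here after their values were seen, reached only 1.39, 1.48 and 1.01 in P5. PRDM14 and TCL1A passed the filter only through P5, and TCL1A was listed at 0 in PEF. Among the factors set in advance, KLF4 (chromosome 1, 279056680 to 279061593) was at 11.6 in PEF and 116 in P5, and MYC (chromosome 4, 12778443 to 12783481) at 40.1 and 493. The sources used here do not say whether introduced copies of KLF4, MYC or LIN28A add to the values. The neural and ectoderm list had 9 of 12 members higher and a median of 1.83, led by ELAVL3, a neuronal RNA-binding protein, at 0.0658 in PEF and 21.8 in P5. Trophectoderm genes had a median of 1.04 with 4 higher and 3 lower of 8, and KRT8 and KRT18, which the epithelial list also holds, led them. That list was inside the random range under quantile normalization, without the filter on low FPKM and without IDs sharing a locus. Of 19 oxidative phosphorylation genes, all of the nuclear genome, 5 were higher and the median was 0.86. COX5A, a subunit of cytochrome oxidase, was at 25.4 in PEF and 86.2 in P5. Genes of the mitochondrial genome, named after their values were seen, went both ways, from COX2 at 1.14 to ND5 at -1.52.

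Of the 30 fibroblast and extracellular matrix genes, 27 were lower in P5 than in PEF, with a median of -4.36. COL1A2, a chain of type I collagen, was at 1266 in PEF and 5.83 in P5, and THBS2, a matrix glycoprotein, at 365 and 0.322. Of the 3 higher members, FBLN1, named after its value was seen, was at 1.34 in PEF and 21.4 in P5. FN1 and THBS1, the others, were listed at 0 in PEF, and no difference is drawn for them because an exact 0 can be a failed estimate. Both still enter the counts and the median of the list. All 10 contractile and smooth muscle genes were lower, with a median of -5.86. Of 9 mesenchymal transcription factors, 6 were lower and 1 was higher, with a median of -1.52, and PRRX2 was at 104 in PEF and 1.11 in P5. The higher member was MEOX2, at 3.21 in PEF and 15.2 in P5. With a mean FPKM of at least 5, this list was inside the random range and the naive-associated list had fewer than 5 members to place. The naive-associated list was also inside the range with a pseudocount of 5.

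LIF and STAT3 genes had a median of -1.64, with 8 of 12 lower and 0 higher. JUNB, an AP-1 subunit induced by cytokines, was at 68.7 in PEF and 6.27 in P5, and STAT3 itself was at 154 and 30.2. Interferon response genes had a median of -1.19, with 8 of 14 lower and 1 higher, and MX1, an antiviral GTPase, was at 55.6 and 12.4. TGF-beta, activin and BMP genes had a median of -0.61, with 11 of 24 lower and 3 higher. LTBP1, which binds latent TGF-beta, was at 188 in PEF and 14.0 in P5, and FST, the activin antagonist follistatin, was at 3.85 and 112. This list was inside the random range under quantile normalization, without IDs sharing a locus and with a mean FPKM of at least 5.

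The other lists had medians inside the random range in P5 minus PEF. These medians were 0.49 for mesoderm, 0.91 for germ cell, 0.57 for DNA methylation, 0.42 for Polycomb, 0.30 for histone deacetylase and 0.07 for histone methyltransferase and demethylase genes. They were -0.21 for p53 targets, -0.62 for glycolysis, 0.68 for FGF and ERK, 0.59 for WNT, 0.41 for imprinted, 1.40 for endothelial and -0.52 for stress genes. The mean had the opposite sign for WNT genes, at -0.05, and for histone methyltransferases and demethylases, at -0.02. Single members stood apart: UHRF1, which guides maintenance methylation, was at 9.31 in PEF and 122 in P5, and CBX2, a Polycomb subunit, at 1.37 and 17.2. Of the endothelial markers, PECAM1 was at 2.78 in PEF and 12.8 in P5, and ENG was at 16.7 and 2.91. Endoderm and immune markers had 3 and 2 members compared, too few to place, with medians of 0.58 and -0.56.

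In all, 5734 genes differed by at least 1 between P5 and PEF, 2990 higher and 2744 lower in P5. The balance turned with trimmed-mean scaling, to 2742 higher and 2927 lower, and with a pseudocount of 5, to 1416 and 1826. Of the 5734, 415 had an FPKM of 0 in 1 of the 2 groups. Of the 27 lists placed, 8 lay above and 6 below the random range. The largest differences by the rule also included BEX4 (5.43 in PEF and 1249 in P5), BEX1 (3.56 and 531), IGFBPL1 (0.869 and 178) and APOE (2.63 and 296) on the higher side. The lower side included ASPN (598 and 0.845), CCL2 (1061 and 3.11) and CCN3 (427 and 1.21). APOE and ASPN lie at loci shared by 6 and 7 IDs. The small nucleolar RNA genes SNORA30, listed at 0 in PEF, and SNORD8, listed at 0 in P5, also met the rule.

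**Figure D1:**
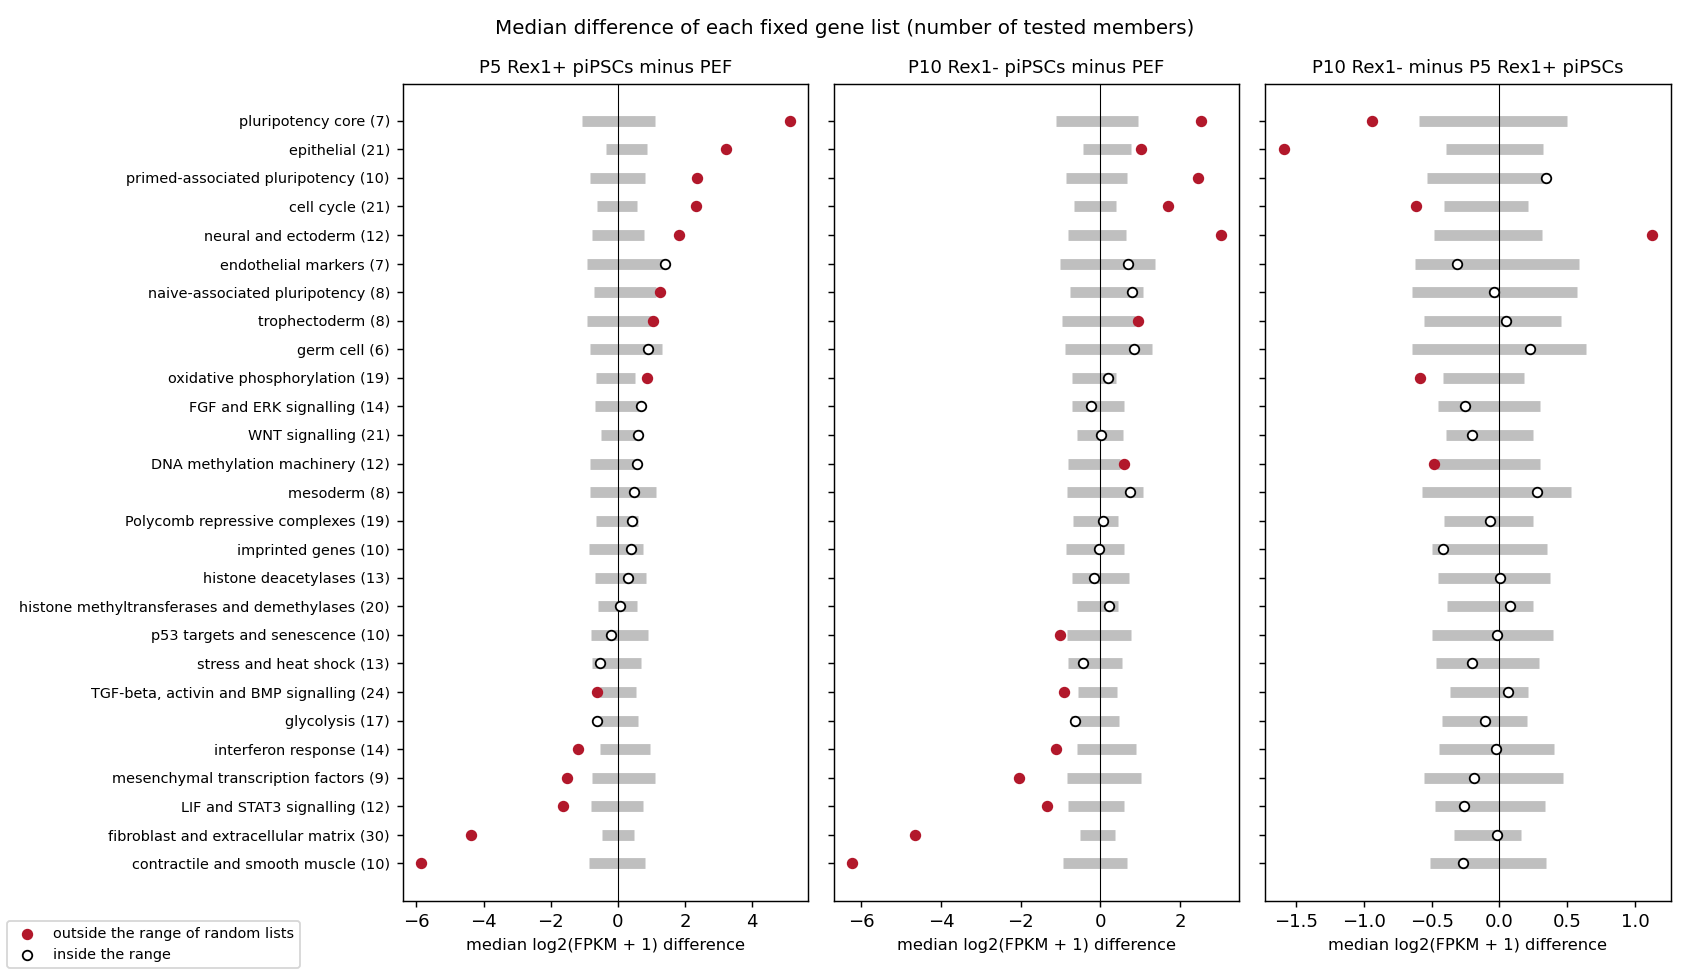
Median difference in log2(FPKM + 1) of each gene list (horizontal axis) in the 3 comparisons, with the number of compared members after each name. Grey bars span the random range from 10000 lists and red points lie outside it, as the epithelial list does at 3.23 (P5 minus PEF), 1.02 (P10 minus PEF) and -1.59 (P10 minus P5).

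The second comparison, P10 against PEF, asked the same of the later Rex1 negative piPSCs. LIN28A, KRT8, KRT18 and cell cycle genes were again higher than in the fibroblasts, and matrix and contractile genes were lower. IGFBPL1, a member of the IGF-binding protein family (chromosome 1, 267175370 to 267190286), was at 0.869 in PEF and 395 in P10, a log2 difference of 7.73. LMX1A, a transcription factor of midbrain and roof plate development, was at 0.113 and 159, and FABP7, a fatty acid-binding protein of neural progenitors, at 0.343 and 114. COL3A1, a fibrillar collagen of fibroblasts (chromosome 15, 104067017 to 104105776), was at 1016 in PEF and 3.11 in P10.

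The neural and ectoderm list had a median of 3.03 in P10 minus PEF, with 9 of 12 higher and 1 lower. STMN2, a neuronal microtubule regulator, was at 19.7 in PEF and 594 in P10, and the lower member was LHX2, at 2.49 and 0.05. Pluripotency core genes had a median of 2.53, with 6 of the 7 compared, out of 24 listed, higher, and LIN28A was at 204 in P10. Primed-associated genes had a median of 2.46, with 8 of 10 higher and 2 lower, and OTX2 was at 63.0 in P10. Cell cycle genes had a median of 1.70, with 18 of 21 higher. Of the epithelial list 11 of 21 were higher and 0 lower, with a median of 1.02. This median was inside the random range under quantile normalization and with a pseudocount of 5. Among the higher members, 1 of this list and 1 of the pluripotency core list were listed at 0 in PEF. DNA methylation genes had a median of 0.60, with 5 of 12 higher and 2 lower, and were inside that range under quantile normalization. Trophectoderm genes had a median of 0.94, with 4 of 8 higher and 2 lower, and were inside it without the filter on low FPKM and without IDs sharing a locus. KLF4 was at 299 and MYC at 981 in P10.

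On the lower side, fibroblast and extracellular matrix genes had a median of -4.66, with 27 of 30 lower, and contractile genes one of -6.23, with 10 of 10 lower. ACTG2, the enteric smooth muscle actin, was at 1911 in PEF and 5.94 in P10. Mesenchymal transcription factors had a median of -2.03, with 8 of 9 lower and 0 higher. LIF and STAT3 genes had a median of -1.35 with 10 of 12 lower, and OSMR, a receptor chain for oncostatin M, was at 20.6 and 0.173. Interferon genes had a median of -1.11 with 10 of 14 lower, and TGF-beta, activin and BMP genes one of -0.90 with 11 of 24 lower and 3 higher. TGFBR2, the type II TGF-beta receptor, was at 40.5 in PEF and 0.889 in P10. p53 targets and senescence genes had a median of -1.02, with 6 of 10 lower and 1 higher. Of 22 genes on that list only these 10 were compared. CDKN1A, named after its value was seen, was listed at 0 in all 3 groups and did not enter. With a mean FPKM of at least 5, the p53 and mesenchymal factor lists were no longer outside the random range.

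Inside the random range were the naive-associated (median 0.79), mesoderm (0.74), germ cell (0.83), Polycomb (0.08), histone deacetylase (-0.16), histone methyltransferase and demethylase (0.21), glycolysis (-0.63) and oxidative phosphorylation (0.19) lists. So were the FGF and ERK (-0.23), WNT (0.03), imprinted (-0.03), endothelial (0.71) and stress (-0.44) lists. The mean had the opposite sign for WNT genes, at -0.34, and for endothelial genes, at -0.60. Endoderm and immune members, too few to place, had medians of 0.45 and 0.15. In all, 5383 genes differed by at least 1, 2678 higher and 2705 lower in P10 (2844 and 2567 under median scaling, 1249 and 1762 with a pseudocount of 5), and 7 lists lay above and 7 below the random range. By the rule the largest differences also held BEX4 (591 in P10), CCL2 (1.94), PTGS2 (502 in PEF and 1.08 in P10) and COL8A1 (1597 and 6.05). ESR1, the estrogen receptor alpha gene, was listed at 0 in PEF and P5 and at 133 in P10.

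Both piPSC groups were then compared for shared genes against PEF. Of the genes higher than in PEF, 1747 were higher in both groups, and 2085 were lower in both. Independent lists of the same sizes would share 572 and 530. A further 12 genes were higher in P5 and lower in P10 than PEF, and 14 were the reverse, against 578 and 525 for independent lists. Both comparisons use the same PEF column, so independent lists do not give the numbers for unchanged groups. With 1 value per group that column could not be split, nor simulated with a measured spread. Part of the excess may come from the shared PEF values.

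**Figure D2:**
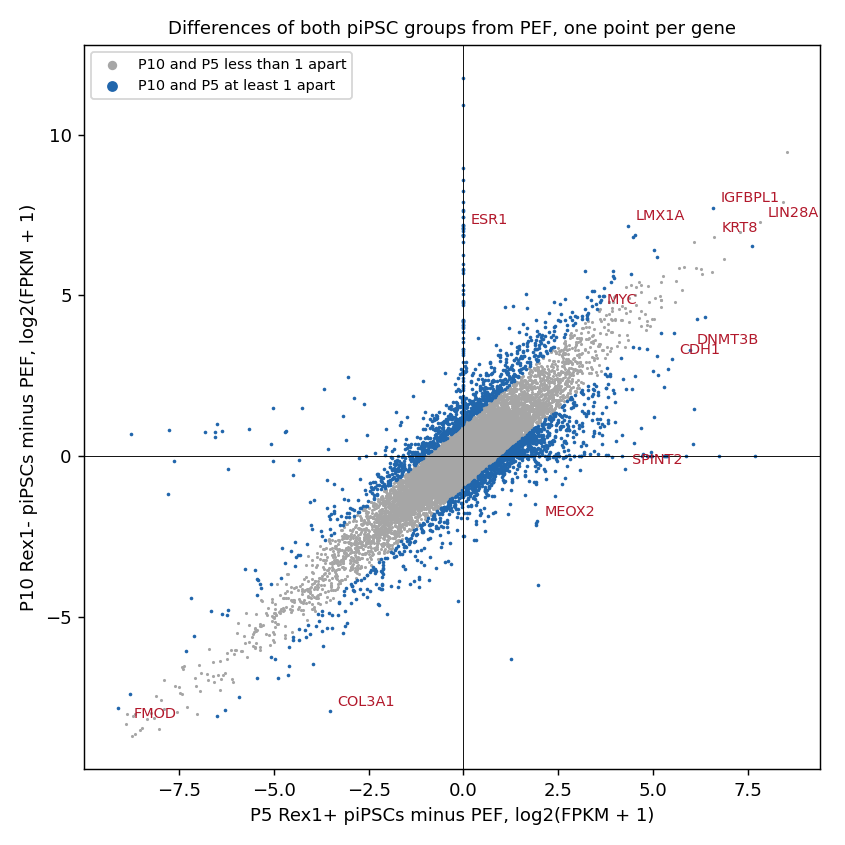
Difference of P5 from PEF (horizontal axis) against difference of P10 from PEF (vertical axis), both in log2(FPKM + 1), 1 point per gene compared. Blue points are the 2247 genes at which P10 and P5 differed by at least 1, among them COL3A1 (-3.52 and -7.95), LMX1A (4.35 and 7.17) and SPINT2 (4.26 and -0.41).

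The third comparison, P10 against P5, asked how the later Rex1 negative piPSCs differed from the earlier Rex1 positive ones. The medians of the epithelial, pluripotency core, cell cycle, oxidative phosphorylation and DNA methylation lists were lower in P10 and that of the neural list was higher. SPINT2, an epithelial protease inhibitor (chromosome 6, 42701292 to 42710420), was at 37.9 in P5 and 0.535 in P10, a log2 difference of -4.67. DNMT3B was at 159 and 24.4, a difference of -2.66. DCX, a microtubule protein of migrating neurons, was at 8.04 in P5 and 44.4 in P10, and LMX1A (chromosome 4, 93227596 to 93275883) was at 21.7 and 159. Passage and Rex1 state differed together between these groups and cannot be separated.

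Of the epithelial list, 13 of 21 members were lower in P10 and 0 were higher, with a median of -1.59 at percentile 0 of the random lists. CLDN4, a tight junction claudin, was at 38.0 in P5 and 1.79 in P10, and EPCAM was at 41.6 and 6.07. KRT8 and KRT18 differed by 0.21 and -0.30 and were not counted. Pluripotency core genes had a median of -0.94, with 3 of 7 lower and 0 higher. The lower ones were DNMT3B, EPCAM and CDH1, which was at 48.7 and 7.89. EPCAM and CDH1 are also in the epithelial list and DNMT3B in the DNA methylation list, so these 3 lists are not independent. The other 4 core members lay between. Of 24 core genes listed only 7 were compared, without POU5F1, SOX2 and NANOG. LIN28A differed by -0.55. Cell cycle genes had a median of -0.62, with 3 of 21 lower, among them MCM5, at 20.6 and 5.63.

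Oxidative phosphorylation genes, a list of nuclear genes only, had a median of -0.58, with 5 of 19 lower and 0 higher. COX5A was at 86.2 in P5 and 32.6 in P10. Genes of the mitochondrial genome went both ways, from ATP8 at 1.66 to ND4L at -0.36. Both lie at shared loci and were named after their values were seen. DNA methylation genes had a median of -0.48, with 2 of 12 lower, DNMT3B and MBD2, a reader of methylated DNA, which was at 16.1 and 6.09. That list was inside the random range without the filter on low FPKM and without IDs sharing a locus. The neural and ectoderm list was higher, with a median of 1.12 at percentile 100, 7 of 12 higher and 1 lower. NCAM1, a neural adhesion molecule, was at 55.5 and 145, PAX3, a neural crest factor, at 8.92 and 24.5, and the lower member LHX2 at 1.34 and 0.05.

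**Figure D3:**
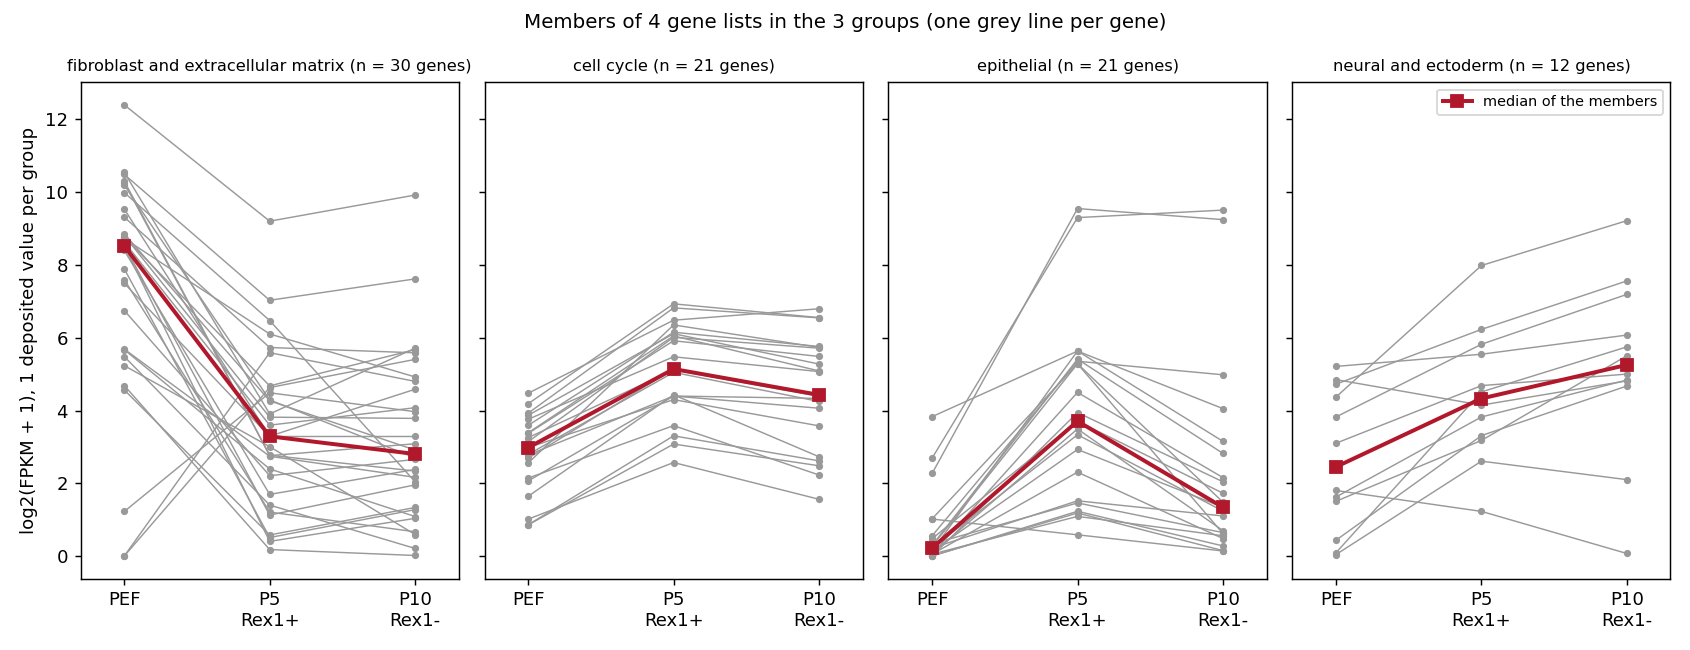
Values of the compared members of 4 lists in the 3 groups, as log2(FPKM + 1) on the vertical axis, with 1 grey line per gene and the median of the members in red. The epithelial median was higher in P5 than in PEF and P10, and the neural and ectoderm median was highest in P10, where DCX reached an FPKM of 44.4.

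The remaining lists lay inside the random range in P10 minus P5, although some members differed. Primed-associated genes had a median of 0.34 at percentile 96.9, with ZIC2 (31.7 and 109) and ZIC5 (16.6 and 35.0) among the higher members. Naive-associated genes had a median of -0.04, with KLF4 higher by 1.36 and 3 of 8 lower, and MYC differed by 0.99. The lower members, TBX3, PRDM14 and TCL1A, were at only 1.32, 1.48 and 1.01 in P5. Fibroblast and extracellular matrix genes had a median of -0.02, with COL3A1 at 87.9 in P5 and 3.11 in P10 and BGN, a matrix proteoglycan, at 14.0 and 51.4. Contractile genes had a median of -0.27 and mesenchymal factors one of -0.19, with MEOX2 at 15.2 and 0.0314. Of the WNT list (-0.20), AXIN2, a target of WNT signalling, was at 12.9 and 45.6, and LGR5, a WNT-amplifying receptor, at 7.06 and 0.352. Of the FGF and ERK list (-0.26), ETV4, an ETS factor downstream of FGF, was at 9.05 and 0.696. Of the imprinted list (-0.41), DIRAS3 was at 87.2 and 6.66, and of the endothelial list (-0.31), PECAM1 was at 12.8 and 1.17.

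Further medians in P10 minus P5 were 0.28 for mesoderm, 0.05 for trophectoderm, 0.22 for germ cell, -0.07 for Polycomb, 0.01 for histone deacetylase and 0.08 for histone methyltransferase and demethylase genes. They were -0.02 for p53 targets, -0.11 for glycolysis, -0.26 for LIF and STAT3, 0.06 for TGF-beta, activin and BMP, -0.03 for interferon and -0.21 for stress genes. The mean had the opposite sign for trophectoderm (-0.01), germ cell (-0.08), histone deacetylase (-0.10) and TGF-beta, activin and BMP genes (-0.05). Endoderm and immune members, too few to place, had medians of -0.13 and 0.71.

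In all, 2247 genes differed by at least 1 between P10 and P5, 1060 higher and 1187 lower in P10, or 1151 and 1065 with trimmed-mean scaling and 508 and 705 among symbols without small RNA names. Of the 27 lists placed, 1 lay above and 5 below the random range. The rule for the largest differences took mostly small nucleolar RNA genes on the higher side (SNORA24, SNORD8, SNORA31, SNORA25, SNORA2C, SNORA9 and SNORA12), all listed at 0 in P5, with ESR1. Without small RNA names, a choice made after seeing the data, the higher side held SAG, the visual arrestin, at 2.61 in P5 and 36.8 in P10. It also held S100Z (0.495 and 13.6), TFAP2B (1.85 and 19.6), FILIP1 (4.54 and 36.9), MYMK (0.105 and 6.49) and MSX1, a homeobox gene of neural crest and mesoderm (7.16 and 49.6). The lower side held HENMT1, a small RNA methyltransferase of the germ line (67.5 in P5 and 1.80 in P10), TMEM171 (31.1 and 0.131), TKTL1 (26.0 and 0.0546) and MME (21.5 and 0.349). PAGE4, at 57.0, and ACTL8, at 17.1, had values in P5 and were listed at 0 in PEF and P10. SNORA30 and SNORA13 were listed at 0 in PEF and P10 as well.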

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

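All tests of technical explanations in this part were chosen after the results were seen. The test of scaling between the columns replaced 2 earlier forms whose outcome was fixed by their construction or by the choice of lists. The test of leftover PEF RNA replaced an earlier form, which set the upper quartile of 4.85% against the median need of 6.27%, after its value was seen. COL6A2, HAPLN1, HHIP, ITGA4, SNORA46 and SNORD17 were named after their values were seen. With 1 value per group, the directions against PEF given here were not tested.

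Several genes lay on opposite sides of PEF in the piPSC groups, each by at least 1 on the log2 scale. MME, a membrane metalloendopeptidase, was at 5.02 in PEF, 21.5 in P5 and 0.349 in P10, so that P10 minus P5 was -4.06. HAPLN1, a link protein of hyaluronan matrix, was at 3.70, 16.8 and 0.109, with P10 minus P5 at -4.01. MEOX2, a mesodermal homeobox gene, was at 3.21, 15.2 and 0.0314, with a difference of -3.97. HHIP, a Hedgehog-binding protein, was at 2.07, 10.4 and 0.101, with a difference of -3.37, and ITGA4, an integrin chain, at 1.67, 5.34 and 0.28, with one of -2.31. The small nucleolar RNA genes SNORD17, SNORA46 and SNORA25 were lower in P5 and higher in P10 than PEF, with P10 minus P5 at 2.25, 4.41 and 5.78, and the latter pair was listed at 0 in P5.

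Of 30 fibroblast and extracellular matrix genes, 7 were lower in P10 than in P5, 2 were higher (BGN by 1.81 and COL6A2 by 1.29) and 21 lay between, with a median of -0.02 inside the random range. If PEF RNA left over in the P5 samples were the whole cause for the lower ones, such as COL3A1 (87.9 in P5 and 3.11 in P10), P5 would need to hold from 1.12% (COL5A2) to 17.8% (FBLN5) of the PEF level. Leftover RNA would bring every abundant PEF transcript, yet over the 79 genes with at least 100 FPKM in PEF and at most 5% of that in P10 the lower quartile of P5 over PEF was 0.719%, with 29 below the smallest share needed, which argues against it as the whole cause. Over all 556 genes with at least 100 in PEF, many of them also high in piPSCs, the lower quartile was 14.8% and 30 lay below that share. A difference between the cells that goes with passage or Rex1 state stays open and was not tested.

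Epithelial genes were lower and neural genes higher in P10 than in P5. After quantile normalization, which gives the columns the same distribution, the epithelial median was -1.70 and the neural median 1.16. With 1 member left out they were -1.64 and 1.09 at their weakest, past the random limits of -0.37 and 0.36. Equal column distributions thus did not remove either difference. Both lists were known to lie outside under this setting when the test was chosen, so it adds no independent support. Fibroblasts mixed into P10 would have to make up 80.8% to give the median FPKM ratio of P10 to P5 over 21 epithelial genes, 0.192, or 66.8% to give their median log2 difference of -1.59. Over the 72 genes with at least 100 FPKM in PEF and at most 5% of that in P5, the median of P10 over PEF was 1.23%, with an upper quartile of 3.63%, which argues against such a share. Over all 556 genes with at least 100 FPKM in PEF, many of them also high in piPSCs, the median was 48.7%. Their upper quartile was 99.7%, and 379 lay below 80.8%. Passage, Rex1 state and other cell types in the P10 cultures stay open and were not tested.

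Of 69 small RNA names, 19 had a value above 0 in P5, against 26 in PEF and 31 in P10. This is the order of the relative depth drawn from low values. A lower depth of the P5 column is therefore a candidate explanation for zeros such as those of SNORA24 and SNORA31. Zeros over all IDs did not follow that order, at 9141 in PEF, 8456 in P5 and 7799 in P10. Zeros beside at least 20 FPKM in both other groups did, at 13, 16 and 1. SNORA30 went against it, at 105 in P5 and 0 in PEF and P10. The order of 3 columns is weak evidence, and neither the handling of short genes by the authors' program nor a difference in the cells was tested.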

How the results depend on the processing

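No paired analysis was possible because the table has 1 column per group and the columns carry no replicate number. For the same reason the planned fits without an intensity trend, on 4 libraries, with a replicate block, at other adjusted p thresholds or with a library left out were not run, nor were camera, fry, edgeR and DESeq2. No difference of a named gene turned its direction under any alternative run, and no list moved to the opposite side of the random range. The balance of higher and lower genes, close to even as reported, did turn. In P5 minus PEF 52.1% of counted genes were higher as reported, against 48.4% with trimmed-mean scaling, 43.7% with a pseudocount of 5, 46.4% with a mean FPKM of at least 5 and 46.3% at a log2 difference of at least 2. In P10 minus PEF 49.7% became 52.6% under median scaling and 52.5% with a pseudocount of 0.1, and moved further the other way, to 41.5% with a pseudocount of 5 and 43.1% with a mean FPKM of at least 5. In P10 minus P5 47.2% became 51.9% with trimmed-mean scaling, 50.3% under quantile normalization and 50.6% with a pseudocount of 5, and moved further the other way, to 41.9%, with symbols but without small RNA names. With a mean FPKM of at least 5 the median difference over all genes turned from 0.09 to -0.01 in P5 minus PEF and from 0.06 to -0.06 in P10 minus PEF. The count of lists outside the random range stayed at 11 to 15 for P5 minus PEF, 12 to 15 for P10 minus PEF and 5 to 7 for P10 minus P5, over all settings but the log2 difference of at least 2, which does not enter it. Single lists lost their place outside the range, as given with their results, and others gained one. With a mean FPKM of at least 5 only 23 lists had enough members to be placed, against 27 as reported and 29 without the filter. Counts of genes stayed within 1.5 times under median, quantile and trimmed-mean scaling, without IDs listed at 0 and without IDs sharing a locus. Removing the filter added no gene by construction, since with a pseudocount of 1 a gene under 1 FPKM in both groups cannot differ by 1.

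Counts that moved further did so as the settings are built, by admitting or removing low genes, raising the threshold or dropping IDs. With a pseudocount of 0.1, P10 minus P5 counted 3418 genes. A pseudocount of 5 gave 3242 for P5 minus PEF, 3011 for P10 minus PEF, 878 for P10 minus P5 and 2139 shared in direction between both piPSC groups (3832 as reported). A mean FPKM of at least 5 gave 3495 for P10 minus PEF and 1366 for P10 minus P5. A log2 difference of at least 2 gave 2042, 2031, 374 and 1380 in the order of the second setting, and symbols without small RNA names gave 3624, 3391, 1213 and 2484. Of 418 values of named genes, 91 dropped below a difference of 1 with a pseudocount of 5, 18 under quantile normalization, 6 under trimmed-mean and 5 under median scaling. The unknown depth limits low values most, and a spread between libraries could not be set beside any value.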

Other observations

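The 2 lists of genes tested in this part were written, with their tests, before their values were seen, after the lists of the main comparisons had been examined. They share no gene with those. Names in this part other than FN1 and THBS1 were chosen after their values were seen.

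A second neuronal list asked whether the higher neural genes of P10 extend beyond the list already described. Its median in P10 minus P5 was 0.61 at percentile 99.99 of random lists, which is consistent with the hypothesis that neuronal genes are higher in P10 more widely. Few members differed by at least 1: SYP, a synaptic vesicle protein, at 6.32 in P5 and 20.5 in P10, and DLG4, a postsynaptic scaffold, at 7.27 and 23.2, were higher. NEFL, a neurofilament chain, was lower, at 14.4 and 4.32, and the other 22 of 25 members lay between. Many members had low values, whose precision is unknown. Some passed the filter only through P10, such as GAD2, at 0.336 in P5 and 1.08 in P10. Higher neural genes in P10 had been seen in the same columns before the list was written, so it is no independent test. Neither this list nor the next was placed under the alternative settings.

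A motile cilium list had a median of 0.56 in P10 minus P5 at percentile 99.92, with 9 of 25 members higher and 1 lower, so the data are consistent with higher cilium genes in P10 as a hypothesis. ODAD4, a dynein docking factor, was at 13.5 in P5 and 39.9 in P10, and CFAP161 at 0.346 and 4.71. DNAH11, a ciliary dynein chain, was lower, at 1.58 and 0.258. Most members had low values, whose precision is unknown, and some, CFAP161 among them, passed the filter only through P10. Cilium-associated genes had been seen among the genes highest in P10 over P5 before the list was written. The list follows up that pattern in the same columns and is no independent test of it.

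Zeros beside high values differed in number between the columns. Of IDs with an FPKM of at least 20 in both other groups, 13 were listed at 0 in PEF, 16 in P5 and 1 in P10. Those in PEF included FN1, THBS1 and SOX21, and FN1 is ordinarily abundant in fibroblasts.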
